A study of Sus scrofa with 8 samples.

How the data were processed

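Whole blood from 8 sows (Sus scrofa) was drawn 14 days after insemination, 4 from sows that were pregnant and 4 from sows that were not, all of the fifth parity. Per the labels' protocols, blood was mixed with lysis solution soon after collection, total RNA was extracted and column purified, RNA was admitted only above a set integrity score, and Cy3-labelled cRNA was made with a low-input labelling kit. Each sow has 1 single-colour Agilent porcine array. The design text describes 3 half-sib pairs and 1 unrelated pair, with 4 sows from each group. The labels do not say that the replicate number marks such a pair. The arrays lay on 2 slides, each scanned once, and each slide held 2 arrays of each group, replicates 1 and 3 on slide 1 and replicates 2 and 4 on slide 2.

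The authors deposited 1 scanner file per array, made with Agilent Feature Extraction 10.7.3.1 per the file headers and 10.7 per the submitters' processing notes. Its processed signal is a spot intensity on a linear scale, background-subtracted and spatially detrended per the file headers, with no normalization between arrays. The same files give the median intensity of each spot and of its local background, per the file headers. The authors also deposited a table of log2 values, whose normalization is not given in the sources used here. Each of its columns correlated with log2 of the processed signal of its own array (Pearson r of 0.99895 or higher across probes), and all 8 columns had a lower quartile of 2.19, a median of 5.03 and an upper quartile of 7.76. That shape is what quantile normalization gives, and the direction is that of the signal. What stays unknown is how the table was centred and which software made it. It served only as an alternative.

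Control spots and spots marked by the scanner as outliers were left out, and spots of 1 probe were averaged on the log2 scale. Each array's log2 signals were taken relative to their 75th percentile. Of 43603 probes, 215 had every spot marked on some array and were dropped. Probes well above background on all 4 arrays of at least 1 group were kept, which left 26481 probes (60.7%). Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Tables were read with pandas 2.3.3 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.

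The scanner files pair probes with accessions and not with gene symbols. Of 5779 probes with a RefSeq transcript accession, 5461 were matched to 2389 symbols in a table of the Sscrofa11.1 assembly, used for names only. The 7535 probes with an Ensembl transcript, the 13941 with a TIGR consensus, the 11213 with another sequence accession and the 5135 with only a probe identifier stayed unnamed. Among the probes kept, 4012 had a symbol. A gene was represented by its brightest probe over all 8 arrays, which gave 1817 genes, 876 of them with a single kept probe. A probe not well above background on any array of a group has only a bound there, and its fold is given as "at least", from the mean of the brighter group against, for each array of the dimmer group, the higher of the probe's value and the lowest signal well above background.

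The test, the samples, 30 gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where a later choice is stated. Lists with at least 5 measured genes, 29 in number, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were the alternatives. List genes without a measured symbol were matched through the name table's synonyms, which added other genes in 4 lists: CELA2A for ELANE, LEPROT for LEPR, NIFK for MKI67, and CYBRD1 and PTGS2 for mitochondrial CYTB and COX2. None of these lists was called. The named genes are up to 10 per direction. Genes past the threshold come first, and the remaining places go by unadjusted p to genes at least 2-fold apart whose groups do not overlap. Up to 4 members of smallest unadjusted p were added from each of 9 lists described, which gave 42 genes, 2 of which are not reported here.

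On values simulated for the 26481 probes with 200 changed, limma recovered 0% of 2-fold changes, 56.5% of 4-fold changes and 87.5% of 8-fold changes. Between 61.7% and 69.2% of probes were well above background on each array, no spot was saturated (0 on each array), and the 75th percentile of the processed signal ran from 142 to 296. The number of arrays limits the precision: the median 95% interval of a gene reached 0.67 on the log2 scale (1.59-fold) to either side.

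Alternatives were quantile normalization, scaling on the median, other filters on dim probes, the slide or the replicate number as a block, each slide alone, array weights, a trended and robust variance, the deposited log2 table, the mean of a gene's probes, and each array left out in turn. Normexp background correction (offset 50) was planned on mean spot signals, a column not used here, and was run on the median signals. Its first fit failed: spots with a very bright local background, where signal minus local background was as low as -61392, pulled the fitted background mean to as low as -811 on non-pregnant replicate 4, against -2.81 on pregnant replicate 1, and r with the processed signal fell to 0.821. All spots this far off carried the scanner's mark for background outliers. The marked backgrounds, 300 to 565 spots per array, were therefore replaced by the array's median background, after which r was 0.969 or higher on every array. This replacement was chosen after the failed fit and its results had been seen.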

Results

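Gene expression in whole blood was compared between 4 pregnant and 4 non-pregnant sows 14 days after insemination, around the time when pig conceptuses have elongated and attach to the uterus. Each sow was measured on 1 array, so the spread within a group holds differences between animals and between arrays, which cannot be told apart. Arrays correlated with each other at r between 0.870 and 0.984 over the probes kept. Pregnant replicate 2 stood apart: it had the lowest 75th percentile signal (142, against 175 to 296 on the other arrays), and without it the lowest r was 0.946. The first principal component held 48.6% of the variance and placed pregnant replicate 2 at 154.52, with the other 7 arrays between -76.81 and 28.98.

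**Figure D1:**
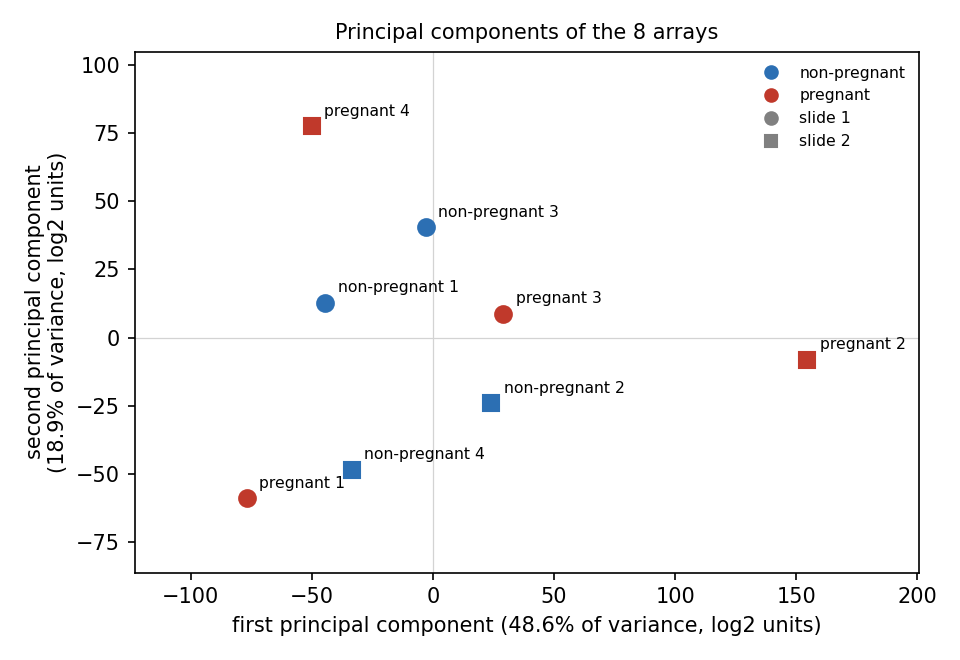
Each point is 1 array, placed by its first principal component (48.6% of variance) and second principal component (18.9%), both in log2 units, with colour for the group and shape for the slide. Pregnant replicate 2 lies at 154.52 on the first component, and neither component parts pregnant from non-pregnant sows.

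Blood of pregnant sows gave a higher signal for 9 genes at least 2-fold apart whose groups did not overlap, although none of them passed the test over all genes. DCT, an enzyme of melanin synthesis, was 3.98-fold higher (95% interval 2.35 to 6.77, limma adjusted p = 0.355), at -0.98 ± 0.42 in pregnant and -2.98 ± 0.58 in non-pregnant sows on the log2 scale (SD, n = 4 each). LPAR3, a receptor for lysophosphatidic acid, was well above background on all 4 pregnant arrays and on 0 non-pregnant arrays, and was at least 2.47-fold higher (limma adjusted p = 0.378). F7, the coagulation factor VII gene, was 2.96-fold higher (95% interval 1.79 to 4.89, limma adjusted p = 0.488). The intervals here and for CYP21A2 below hold for a gene fixed in advance. They do not account for picking these genes by fold, p and separation of the groups, after which folds tend to be too high. No gene that was at least 2-fold lower had groups that did not overlap (0 genes). In either direction and at any fold, groups did not overlap in 26 of the 1817 genes, a smaller share than the 2.86% that chance gives. These 26 include the 9 genes here and CD3D, SH2D1A and CD8A below.

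The other 6 genes had a limma adjusted p of 0.999 each. CYP21A2, an enzyme of cortisol synthesis, was 4.17-fold higher, with the widest interval of the 9 (1.41 to 12.3). CPEB1, an RNA-binding protein that controls polyadenylation in the cytoplasm, was 3.12-fold higher. Receptors made up most of the rest: RXFP4 of the relaxin family was 2.43-fold higher, P2RY2, which binds extracellular nucleotides, 2.38-fold, and the somatostatin receptor SSTR3 2.04-fold. GPNMB, a glycoprotein of macrophages and melanocytes, was 2.39-fold higher. Second probes existed for DCT, GPNMB and P2RY2 and differed less between groups: their log2 fold changes were -0.13, 0.29 and 0.30, so that the probes of DCT disagreed in direction. All 9 genes differed less on slide 1, where the log2 fold changes were 0.39 to 1.24 (under 1 in 6 genes), than on slide 2, where they were 1.28 to 3.66. RXFP4 and CYP21A2 were lowest on slide 1 (0.39 and 0.46), and 7 of the 9 genes were highest on pregnant replicate 2. Without pregnant replicate 2 that of CYP21A2 was 1.34 in place of 2.06.

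**Figure D2:**
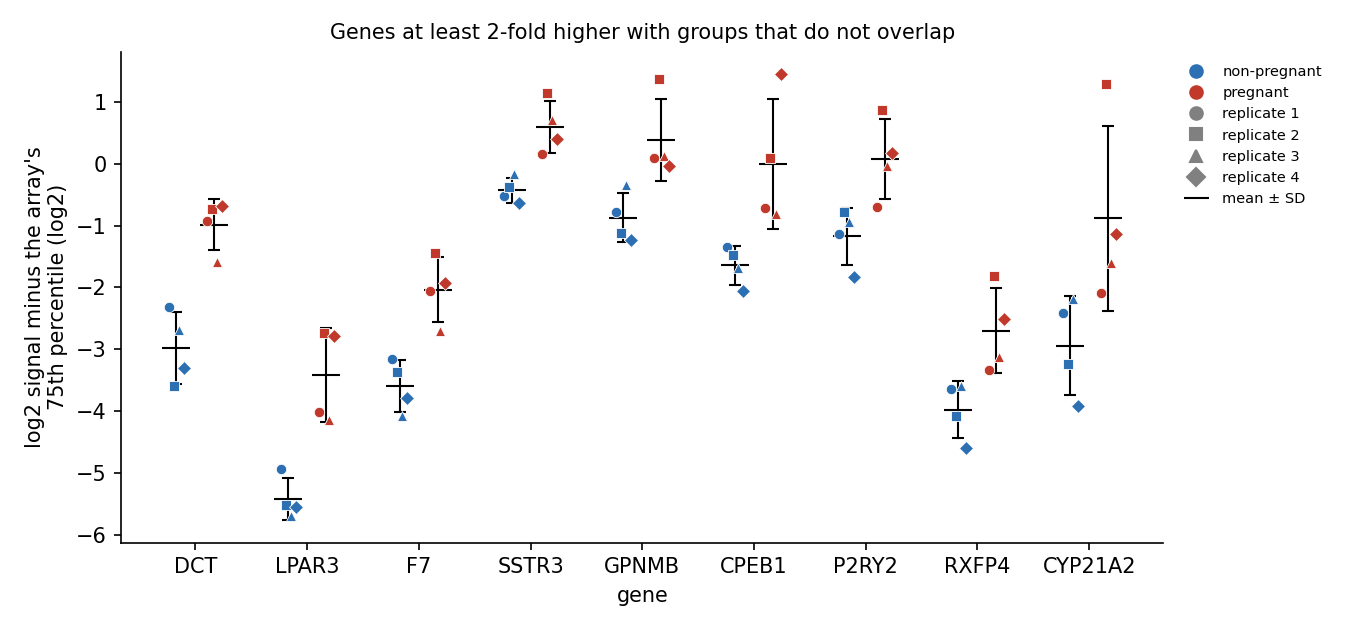
Points are the log2 signal of each array minus its 75th percentile, for the 9 genes at least 2-fold higher in pregnant sows whose groups do not overlap, with bars for the mean ± SD of 4 arrays per group. All 4 pregnant values lie above all 4 non-pregnant values in each gene, none passed the adjusted test, and the non-pregnant values of LPAR3 are not well above background.

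Across all 1817 genes, limma called 0 higher and 0 lower (smallest adjusted p = 0.355). At an unadjusted p under 0.05 there were 44 genes, 29 higher and 15 lower, where 90.85 would be expected with no difference at all. Over the 26481 probes, named or not, the counts were likewise 0 and 0 (smallest limma adjusted p = 0.530), with 607 probes at an unadjusted p under 0.05, 405 higher and 202 lower, against 1324 expected. Groups did not overlap in 418 probes (1.58%, where chance gives 2.86%). Of these, 131 were at least 2-fold higher in pregnant sows and 27 at least 2-fold lower. Without pregnant replicate 4 these counts were 145 and 116, nearly even, without pregnant replicate 1 259 and 74, without non-pregnant replicate 3 270 and 39, without pregnant replicate 2 116 and 42, without non-pregnant replicate 1 148 and 49, and without non-pregnant replicate 2 156 and 44, where chance parts the groups of 3 and 4 arrays in 5.71% of probes. In separate fits on each slide alone, 942 probes on slide 1 and 892 on slide 2 had an unadjusted p under 0.05. These were chosen separately from the 607. Of them, 24.5% were higher in pregnant sows on slide 1 and 85.8% on slide 2.

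Markers of monocytes and macrophages lay higher in pregnant sows as a group. Of 16 measured markers, 15 had a positive log2 fold change, with a median of 0.23, and 0 passed the test singly or adjusted over the list alone. Lysozyme (LYZ) and the haemoglobin scavenger receptor CD163 were each 1.56-fold higher, the endotoxin receptor TLR4 1.35-fold and TLR2 1.25-fold. With an array left out the log2 fold change of CD163 (0.64) ranged from 0.35 without non-pregnant replicate 1 to 1.02 without non-pregnant replicate 2. That of TLR4 (0.43) ranged from 0.28 without non-pregnant replicate 3 to 0.61 without non-pregnant replicate 1. Limma's camera called the list (adjusted p = 0.000818), but the call was lost with an estimated correlation (adjusted p = 0.713). Relative to the median of all genes, the list's median log2 fold change was 0.27 (camera adjusted p = 0.00134 with the slide as a block). Each slide held 2 arrays of each group, so that block cannot change a log2 fold change, here or in the lists below. The median was 0.38 within slide 1 (camera adjusted p = 0.000285) and 0.25 within slide 2 (0.507). Without pregnant replicate 1 it was 0.26 and no longer called (camera adjusted p = 0.203).

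Markers of T cells lay lower in pregnant sows. All 12 measured markers had a negative log2 fold change, with a median of -0.25, and 0 passed the test singly or adjusted over the list alone. The T cell receptor chain CD3D was at 0.661 times its non-pregnant level, the signalling adaptor SH2D1A at 0.727, the kinase LCK at 0.745 and the helper cell marker CD4 at 0.743. Without pregnant replicate 2 the log2 fold change of CD4 was -0.17 in place of -0.43 and that of CD3D -0.39 in place of -0.60. At the probe used for each gene, all 4 pregnant values of CD3D and SH2D1A lay below all 4 non-pregnant values. Second probes differed less, with log2 fold changes of -0.22 for CD3D and -0.068 for LCK, where the probe used gave -0.42. Camera called the list (limma, adjusted p = 0.000818), and an estimated correlation did not (adjusted p = 0.803). The list's median relative to all genes was -0.22 with the slide as a block (camera adjusted p = 0.00134), -0.14 within slide 1 (0.60) and -0.39 within slide 2 (0.00770). Without pregnant replicate 2 it was -0.14 and not called (camera adjusted p = 0.115).

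Markers of cytotoxic lymphocytes and NK cells lay lower too. Of 11 measured, 10 had a negative log2 fold change (median -0.29), and 0 passed the test singly or adjusted over the list alone. CD8A, the co-receptor of cytotoxic T cells, was at 0.677 times its non-pregnant level, with all 4 pregnant values below all 4 non-pregnant values. The granule proteases GZMB and GZMH were at 0.527 and 0.611, and the chemokine CCL5 at 0.675. The log2 fold change of GZMH was -0.34 without pregnant replicate 3 in place of -0.71, and that of CCL5 -0.34 without non-pregnant replicate 2 in place of -0.57. With array weights the log2 fold change of GZMB was 0.19, opposite in sign. Camera called the list (limma, adjusted p = 0.00964), and an estimated correlation did not (adjusted p = 0.803). The list's median relative to all genes was -0.26 with the slide as a block (camera adjusted p = 0.00559), -0.32 within slide 1 (0.120) and -0.53 within slide 2 (0.0521). Without pregnant replicate 1, non-pregnant replicate 2 or pregnant replicate 4 it was -0.31, -0.12 and -0.25, and was not called (camera adjusted p = 0.164, 0.141 and 0.221). Without pregnant replicate 2 it was -0.42 (0.000607) and without non-pregnant replicate 4 -0.46 (0.00163).

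**Figure D3:**
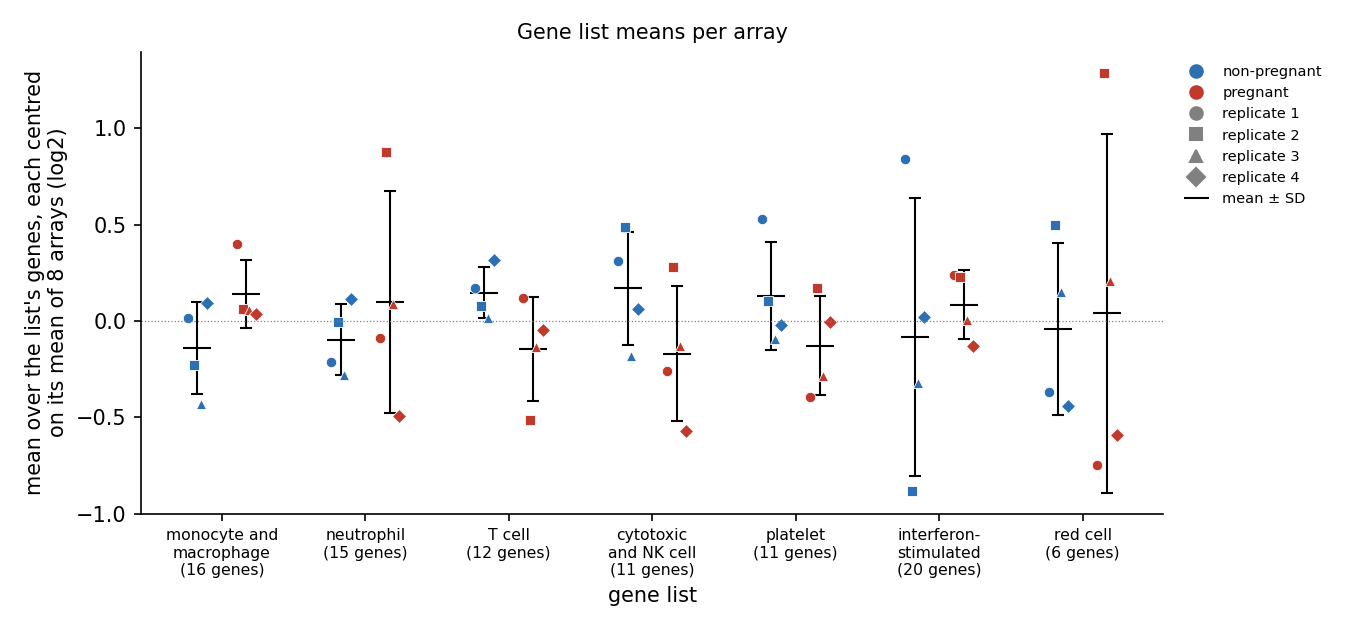
Points are the mean over a list's measured genes on each array, each gene centred on its mean of the 8 arrays (log2), with bars for the mean ± SD of 4 arrays per group. Values of the groups overlap in all 7 lists drawn, and pregnant replicate 2 lies highest for the neutrophil (0.88) and red cell (1.29) lists.

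Neutrophil markers split. Of 15 measured, 11 had a positive log2 fold change (median 0.20): the antimicrobial peptides NPG4 and PMAP-36 were 1.97-fold and 1.70-fold higher, while the gelatinase MMP9 was at 0.469 times its non-pregnant level. The peptides were higher mostly through pregnant replicate 2, where NPG4 stood at 3.07 against 0.16 to 1.16 on the other arrays: without it the log2 fold change of NPG4 was 0.37 in place of 0.98, and that of PMAP-36 0.29 in place of 0.77. That of MMP9 was -0.47 without pregnant replicate 3 in place of -1.09. The list was not called (limma's camera, adjusted p = 0.0927, and 0.819 with an estimated correlation). Its mean on pregnant replicate 2 was 0.88, with the other 7 arrays between -0.49 and 0.12. Relative to all genes its median was 0.24, within slide 1 0.27 (camera adjusted p = 0.0305), within slide 2 0.047 (0.739) and with normexp background correction 0.21 (0.0303). With an array left out it ranged from 0.029 without pregnant replicate 2 (0.780) to 0.56 without pregnant replicate 4, where it was called (0.00768). One of the 15 genes, CELA2A, is a pancreatic elastase matched through a synonym it shares with ELANE. Over the other 14 genes the list's median log2 fold change was 0.30 (camera adjusted p = 0.0558).

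Interferon-stimulated genes were tested because pig conceptuses secrete interferons at about this stage. Of 46 genes listed, 20 were measured. In these, 14 log2 fold changes were positive and 6 negative, with a median of 0.12, and 0 passed the test singly or adjusted over the list alone. OASL and OAS2, which belong to the oligoadenylate synthetase family, were 1.59-fold and 1.39-fold higher, and USP18, a protease that removes ISG15 from proteins, 1.91-fold. Other probes had log2 fold changes of 0.068 to 0.41 for OAS2 and 0.92 for USP18. With an array left out the log2 fold change of OAS2 (0.47) ranged from 0.14 without non-pregnant replicate 2 to 0.84 without pregnant replicate 4. That of USP18 (0.93) ranged from 0.54 without non-pregnant replicate 2 to 1.32 without non-pregnant replicate 4. The list was not called (limma's camera, adjusted p = 0.0705, and 0.915 with an estimated correlation). Sows of the non-pregnant group varied most: the list mean was 0.84 in non-pregnant replicate 1 and -0.88 in non-pregnant replicate 2, against -0.13 to 0.24 in the 4 pregnant sows. The list's median relative to all genes was 0.15 with the slide as a block (camera adjusted p = 0.0734), -0.15 within slide 1 (0.60) and 0.51 within slide 2 (0.00371). It was 0.46 without non-pregnant replicate 1 (3.89e-08), 0.28 without pregnant replicate 4 (0.0312) and -0.070 without non-pregnant replicate 2 (0.787).

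Interferons, their receptors and kinases had 8 measured genes, IFNG among them, and 7 had a positive log2 fold change (median 0.076, camera adjusted p = 0.126, and 0.819 with an estimated correlation). Relative to all genes the list's median was 0.11. It was called at 0.12 with the mean of a gene's probes (camera adjusted p = 0.0473) and at 0.23 without non-pregnant replicate 1 (0.0299). The type I receptor chain IFNAR1 was 1.41-fold higher, with 3 of 4 pregnant values above all non-pregnant ones, IL10RB 1.37-fold and IFNGR1 1.25-fold. Other probes had log2 fold changes of 0.23 for IFNAR1 and 0.49 to 0.61 for IFNGR1. The log2 fold change of IFNAR1 was 0.32 without pregnant replicate 1 in place of 0.50, and without non-pregnant replicate 3 those of IL10RB and IFNGR1 were 0.23 and 0.16 in place of 0.45 and 0.32. The kinase JAK1 was at 0.885 times its non-pregnant level, but its log2 fold change (-0.18) was -0.055 without pregnant replicate 2 and 0.028 when all its probes were averaged.

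Toll-like receptor signalling genes had 12 positive and 9 negative log2 fold changes (median 0.076, camera adjusted p = 0.0547, and 0.803 with an estimated correlation). The ubiquitin ligase TRAF6 was 2.32-fold higher and the adaptor MYD88 1.35-fold (log2 fold change 0.43, and 0.20 without pregnant replicate 4). CD14, TLR2 and TLR4, with log2 fold changes of 0.46, 0.32 and 0.43, belong to the monocyte and macrophage list as well. The Toll-like receptor list lay close to the threshold. Its median relative to all genes, 0.11, was called at 0.087 with quantile normalization (camera adjusted p = 0.0428), at 0.084 with normexp (0.0171), at 0.11 with probes well above background on all 8 arrays (0.0392) and at 0.12 with the mean of a gene's probes (0.0462). Within slide 1 it was 0.19 (0.0307) and within slide 2 0.017 (0.638). With an array left out it ranged from 0.051 without non-pregnant replicate 2 to 0.25 without pregnant replicate 2, and it was called without pregnant replicate 2 (0.00121), pregnant replicate 3 (0.0334), non-pregnant replicate 1 (0.00597) or non-pregnant replicate 4 (0.0477).

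Of 7 measured glucocorticoid- and progesterone-response genes, 5 had a positive log2 fold change (median 0.30, camera adjusted p = 0.0705, and 0.713 with an estimated correlation). The stress-response gene GADD45A was 1.55-fold higher, the metallothionein MT1A 1.47-fold and thrombomodulin (THBD) 1.24-fold. CD163 belongs to this list as well. The list's median relative to all genes, 0.34, was called at 0.30 within slide 1 (camera adjusted p = 0.0252), 0.36 with array weights (0.0376), 0.46 with the mean of a gene's probes (0.0462), 0.29 without pregnant replicate 2 (0.0234) and 0.52 without non-pregnant replicate 4 (0.0344). Within slide 2 it was 0.071 (0.739), with normexp 0.12 (0.0639), and without non-pregnant replicate 1 0.15 (0.0867). The log2 fold change of MT1A ranged from 0.24 without pregnant replicate 2 to 0.90 without non-pregnant replicate 1. That of THBD (0.30) ranged from 0.095 without non-pregnant replicate 1 to 0.59 without non-pregnant replicate 4.

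Maternal recognition and implantation factors had 11 positive and 11 negative log2 fold changes (camera adjusted p = 0.954, and 0.965 with an estimated correlation). The list's median (0.0042) and mean (0.037) were above 0, while the test pointed lower. The cytokine LIF was 2.05-fold higher, the insulin-like growth factor binding protein IGFBP2 was at 0.672 times its non-pregnant level, the angiogenic factor VEGFA at 0.551 and the integrin chain ITGB1 at 0.771. Other probes had log2 fold changes of -0.30 for IGFBP2 and -0.33 to -0.20 for ITGB1. Without pregnant replicate 2 the log2 fold change of LIF was 0.54 in place of 1.04 and that of VEGFA -0.33 in place of -0.86, and IGFBP2 stood at -0.38 without non-pregnant replicate 4 in place of -0.57. In these last 4 lists, and among the neutrophil markers, 0 genes passed the test singly or adjusted over the list alone, and each gene named from the lists had a limma adjusted p of 0.999.

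Of the 29 lists tested, 3 were called, and the other 26 had a camera adjusted p between 0.0547 and 0.957 (limma). With an estimated correlation 0 lists were called (smallest adjusted p = 0.713), and fry called 0 (smallest adjusted p = 0.937). In the simulation over the 26481 probes, where noise was independent between probes, 0% of 2-fold changes were recovered. In that setting, changes of about 2-fold in single probes were below what 4 arrays per group could call. The test over genes was not simulated.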

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

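The fits with an estimated correlation and with each array left out were planned. Their use as tests of whether correlation within lists or a single array accounted for the list calls was chosen only after those calls had been seen.

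In 3 of 108 groups of 4 values, 1 array lay far from the other 3, where chance alone would give about 5.4. GPNMB stood at 1.38 (log2 relative to the 75th percentile) in pregnant replicate 2, against -0.041 to 0.12 in the other pregnant sows. GZMH stood at 2.08 in pregnant replicate 3, against 3.53 to 3.61. The mean of the monocyte and macrophage markers was 0.40 in pregnant replicate 1, against 0.034 to 0.061 in the other pregnant sows.

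The higher monocyte and lower T cell and cytotoxic cell markers form the pattern that a biologist would most want to follow up. Of the 35 splits of the 8 arrays into 4 and 4, 24 called as many lists as the real one (3, with up to 8 in another split), so chance cannot be excluded. With the correlation between a list's genes estimated, the smallest adjusted p of the called lists was 0.713 (limma's camera), which is consistent with co-varying genes being counted as independent ones. None of the 3 lists kept its call in all 8 fits with an array left out. The median relative to all genes did not always shrink much with a lost call. For the monocyte list it was 0.26 in place of 0.27 without pregnant replicate 1. There the median of all genes moved too, from -0.034 to -0.067. For the cytotoxic list it was -0.31 and -0.25 in place of -0.26 without pregnant replicates 1 and 4, and -0.12 without non-pregnant replicate 2. For the T cell list it was -0.14 in place of -0.22 without pregnant replicate 2. The mean over a list did shrink. Pregnant replicate 1 had the highest monocyte mean of the pregnant sows (0.40, group mean 0.14). Pregnant replicates 1 and 4 had the lowest cytotoxic means (-0.26 and -0.57, group mean -0.17). A shift in blood cell makeup with pregnancy stays open and would need cell counts of the same sows.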

How the results depend on the processing

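Normexp with replaced backgrounds, the counts of 2-fold probes under each setting and the matching of list genes by symbol alone were chosen only after the data had been seen, and the others were planned. With symbols alone 3 lists were called, the same 3. Under every alternative, each array left out included, limma called 0 probes and 0 genes past the adjusted threshold. A threshold of unadjusted p under 0.05 with at least 2-fold took 337 probes (272 higher, 65 lower). Of 876 values of the 42 named genes under other settings, 873 kept their sign and 0 passed the threshold. Part of that count was fixed in advance. Blocks on slide or replicate number and the trended variance cannot change a log2 fold change in this balanced design. No array left out and no slide alone could turn the sign of a gene whose groups do not overlap. Among the genes reported, GZMB with array weights (0.19) and JAK1 with the mean of its probes (0.028) did not keep it, and the cause was not tested.

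The count of called lists (3) was 8 with normexp, 5 with quantile normalization, 5 with probes well above background on all 8 arrays, 7 within slide 1, 8 with array weights (whose fit gave a convergence warning), 7 with the mean of a gene's probes, 0 with an estimated correlation, 0 with fry, and 1 to 8 with an array left out. The interferon-stimulated list, at 0.15 relative to all genes, was past the threshold at 0.080 with normexp, at 0.51 within slide 2 and at 0.27 with array weights. It stood at -0.15 within slide 1 and ranged from -0.070 to 0.46 with an array left out. Its adjusted p over all settings reached from 3.89e-08 to 0.937. Maternal recognition factors stood at -0.083 within slide 1, at -0.0085 with array weights, and from -0.022 to 0.18 with an array left out. The cause was not tested. The 131 higher and 27 lower 2-fold probes with groups apart became 14 and 3 with normexp, 215 and 47 with no filter, and 62 and 11 with probes well above background on all 8 arrays. With an array left out the higher ones ranged from 116 to 270 and the lower ones from 35 to 116.

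The normexp fit that failed called 0 probes, 0 genes and 6 lists, 1 of them among the 3, put the interferon-stimulated list at 0.45, and turned the sign of 15 of the 42 genes. With the replicate number as a block, 0 probes, 0 genes and 3 lists were called. The correlation of residuals of same-numbered sows was 0.22, 0.48, 0.43 and -0.12, and only replicates 2 and 3 correlated best with their own number. Replicates 1 and 4 matched across numbers: pregnant replicate 1 correlated best with non-pregnant replicate 4 (0.398), and pregnant replicate 4 with non-pregnant replicate 1 (0.386). The design text has 3 half-sib pairs and 1 unrelated pair, so a correlation below 0 in 1 pair does not rule out that the numbers mark them. As neither the labels nor these values settle it, the numbers were not treated as pairs, and the splits of the arrays were made without regard to them. Signal over background limits LPAR3, RXFP4, CYP21A2, LIF, PMAP-36 and VEGFA, which were not well above background on at least 1 array.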

Other observations

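Tests of pregnant replicate 2 against the slide, the array's signal and solid tissue genes, and the count of splits for 2-fold probes and for adjusted calls, were chosen only after the results had been seen.

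Other blood cell markers gave no call with limma's camera as planned, though some lists did under other settings. Platelet markers had 8 negative of 11 log2 fold changes (median -0.26, adjusted p = 0.0705), B and plasma cell markers 4 of 6 (median -0.20, adjusted p = 0.630), and eosinophil, basophil and mast cell markers 4 of 8 (median -0.097, adjusted p = 0.911). Red cell markers had 4 positive of 6 (median 0.15, adjusted p = 0.557) and dendritic cell markers 3 of 6 (median 0.15, adjusted p = 0.892). Cytosolic ribosomal proteins were negative in 29 of 32 genes (median -0.15, adjusted p = 0.0547), and the mitochondrial respiratory chain in 20 of 24 (median -0.091, adjusted p = 0.158). Genes of class II antigen presentation were negative in 9 of 10 (median -0.17, adjusted p = 0.195) and those of class I in 9 of 13 (median -0.047, adjusted p = 0.957). Cell cycle genes were positive in 6 of 8 (median 0.28, adjusted p = 0.0705). With an estimated correlation none of these 10 lists was called (adjusted p = 0.803 to 0.984).

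Relative to all genes the median of the platelet markers was -0.23, and camera called the list at -0.52 within slide 1 (adjusted p = 0.000334), -0.16 with normexp (0.0303), -0.30 with array weights (0.0189), -0.31 without pregnant replicate 2 (0.0126) and -0.34 without non-pregnant replicate 4 (0.00877). Within slide 2 it was 0.091 (0.824), and that of the ribosomal proteins 0.022 (0.909). The ribosomal proteins, at -0.11, were called in 9 other settings: normexp (0.00103), quantile normalization (0.0396), no filter (0.0161), probes well above background on all 8 arrays (0.0392), slide 1 alone (0.0212), array weights (0.000115), the mean of a gene's probes (0.0462), and without pregnant replicate 2 (-0.21, 0.000415) or non-pregnant replicate 3 (-0.22, 0.000194). The respiratory chain, at -0.057, was called with array weights (-0.19, 0.00194), without pregnant replicate 2 (-0.11, 0.0234) and without non-pregnant replicate 3 (-0.16, 0.00300). Class II genes were called without non-pregnant replicate 3 (-0.27, 0.0447), cell cycle genes without non-pregnant replicate 1 (0.40, 0.00290) and without pregnant replicate 4 (0.31, 0.0221), and lysosome genes within slide 1 (0.34, 0.00486) and without pregnant replicate 2 (0.21, 0.0256), but these stood at -0.24 within slide 2 (0.0521).

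Complement and coagulation genes had 14 positive of 21 log2 fold changes (median 0.10, camera adjusted p = 0.284). F7 was the only gene of any list to pass adjusted over the list alone (limma adjusted p = 0.0169). That adjustment did not cover the other lists, and over all genes F7 did not pass (limma adjusted p = 0.488). C1S, a complement protease, and CD59, which blocks the membrane attack complex, had log2 fold changes of 1.03 and -1.25 and were chosen after their values were seen. Regulatory T cell and tolerance genes were negative in 11 of 18 (median -0.064, adjusted p = 0.460), inflammatory cytokines in 10 of 18 (median -0.073, adjusted p = 0.476), and immediate-early and heat-shock genes, which respond to handling of blood, in 10 of 13 (median -0.12, adjusted p = 0.158). Prostaglandin genes had a positive median of 0.17 and mean of 0.027 while camera pointed lower (adjusted p = 0.922). Steroid receptors and progesterone mediators had a median of -0.039 (adjusted p = 0.631), hypoxia and glycolysis genes -0.019 (0.892) and chaperones 0.15 (0.476). Proteasome subunits (median -0.065, mean 0.034) and lysosome genes (median -0.022, mean -0.0059) both tested higher (adjusted p = 0.911 each). No mitochondrially encoded gene was measured under its symbol (0 genes), and that list was not tested.

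A count of 2-fold probes with groups apart as large as the 131 higher ones (against 27 lower) came in 1 direction in 8 of 35 splits. It reached up to 1256 in another, so chance cannot be excluded for that count. The excess of higher over lower probes was not itself compared between splits. Scaling on the 75th percentile is an unlikely cause, since the ratio was 5.14 with quantile normalization. Pregnant replicate 2 alone does not account for it either, as the ratio was 2.76 without that array. Without pregnant replicate 4 the counts were 145 higher and 116 lower, nearly even. The higher count did not fall, while the lower one rose from 27. Chance parts groups of 3 and 4 arrays more often (5.71% of probes against 2.86%). The ratio thus depends on that array, but the higher count does not. Slides differed too: in separate fits on each slide alone, 24.5% of 942 probes at an unadjusted p under 0.05 were higher on slide 1. On slide 2 it was 85.8% of 892 probes, chosen separately. A difference between pregnant and non-pregnant sows stays open.

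Pregnant replicate 2 stood apart from the rest on the first principal component. The slide is an unlikely cause, because all 3 other arrays of its slide lay within the range of the other slide. Low signal is a candidate explanation that stays open: over 8 arrays the component correlated with the log2 75th percentile signal at r = -0.717 (exact permutation p = 0.0572; Spearman's rho -0.381, p = 0.36), over the other 7 at -0.20 (exact permutation p = 0.691), and without the 2 arrays of most extreme signal at 0.436 (exact permutation p = 0.443), so the relation rests on those arrays. Transcripts of solid tissues cannot be told apart from other causes. Of a list of 128, written after the component's genes were seen, 69 were measured and 66 tested (without genes named for the contrast). Each gene's deviation from its own level over the 8 arrays was taken, which is not its brightness against other genes. On pregnant replicate 2 the median deviation of the 66 genes exceeded that of all genes by 1.27 (log2). The excess was at most 0.50 in another array, but the other 7 spread from -0.97 to 0.50. Between the groups the 66 genes tested higher in pregnant sows (camera p = 0.00474, and 0.475 with an estimated correlation) but at a median log2 fold change of -0.27 without that array (p = 0.107). The brightest, MBP, was at 10.78 there and at 7.46 to 9.96 elsewhere, and as MBP, APOA5 (3.42 or higher) and OPALIN (3.46 or higher) were bright on every array, it is unsure whether their probes measure the transcripts they are named for.

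As many probes at an unadjusted p under 0.05 as in the real comparison (607) came in 24 of 35 splits, with up to 4587 in another, so chance cannot be excluded. The same count for adjusted calls decides nothing, since no split can have fewer than the real 0 (35 of 35 reached it, with up to 145 in another). The split that set replicates 1 and 4 of both groups against replicates 2 and 3 called 145 probes and 28 genes. That points to a structure among the sows or their arrays that crosses the groups. With 1 array per sow, the 2 cannot be told apart. The slide is not that structure, as the split between slides called 0 probes and 0 genes. The solid tissue genes part the same sows (0.32 to 1.27 against -0.97 to -0.30), but so does the first component (-3.04 to 154.52 against -76.81 to -33.44). As that list was written after the component's genes were seen, this adds no support. What sets those sows or their arrays apart, kinship included, stays open.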
